A study of Rattus norvegicus with 21 samples.

How the data were processed

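Liver RNA from 21 male Wistar rats was measured on Illumina bead arrays with 22523 probes. Per the labels, rats received weekly intraperitoneal DEN at 50 or 100 mg/kg or PBS for 18 weeks, a subset received erlotinib at 2 mg/kg or vehicle 5 times per week in weeks 13 to 18, and a separate study used erlotinib at 0.5 mg/kg. The vehicle rats of both studies were combined, per the labels, and the labels name no study for each rat. The labels give total RNA extracted with TRIzol from non-tumour liver. They give the time points of the arrays as weeks 12 and 18 and the times of killing as 9, 13 and 19 weeks, and the names of the labels are used here.

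Both tables hold intensity values on a linear scale. The raw intensity table deposited by the authors holds bead signals without background subtraction, detection p-values or control probes, and the scanner software is not given in the sources used here. The normalized intensity table deposited by the authors has array medians of 135.5 to 136.8, each column keeps the probe order of its own raw column (Spearman correlation 0.99981 to 0.99996), and its normalization method is not given in the sources used here. Raw array medians ranged from 105 to 186.9, and correlations between pairs of arrays after normalization from 0.9027 to 0.9908. Signal over background limits what a bead array can resolve, so genes near background give changes that are lower limits.

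Raw intensities were background corrected in R 4.3.3 with limma 3.58.1 (normexp, offset 50), put on a log2 scale and quantile normalized. Probes above the 40th percentile of their array on at least 3 arrays were kept, and the brightest probe stood for a gene, which left 19335 features, 12108 named genes and 7227 probes without a gene name. Of 22523 probes, 13793 carried a gene symbol, and the Entrez identifiers of 13752 were found in a RefSeq gene table of assembly GRCr8, which served for names alone. A gene counted as near background where its group mean lay at or below 6.38, the median of all normalized log2 values.

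Group means were fitted with limma over all 21 arrays in 7 groups of 3, with 14 residual degrees of freedom, and compared with limma's moderated test. A feature counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Comparisons were made for each DEN dose against PBS, between the DEN doses, for each erlotinib dose and both together against vehicle, between the erlotinib doses, for each erlotinib group against PBS, over time within PBS and DEN 50, and for the interaction of DEN 50 and time. These comparisons, and the alternatives below other than those said to be added, were fixed before the data were examined. In all, 35 lists of pathway and cell type genes (746 genes, 617 matched, at least 5 measured members each) were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The count of list members is given at p adjusted over all features and, where stated, over the list alone. List scores per array were compared with exact two-sided permutation tests, which cannot go below 0.1 for 3 against 3 arrays or 0.0119 for 6 against 3. Correlations between comparisons that share arrays were set against 100 simulations of unchanged groups.

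Genes are named by a fixed rule: the 10 highest and 10 lowest log2 changes among called genes whose arrays do not overlap (5 and 5 by the moderated statistic where fewer than 5 pass), 17 genes chosen in advance, of which 2 have no named probe, and up to 4 members per list with the largest changes. Not every gene under the rule is named in the text. The clock genes other than Per2 were chosen after their values were seen.

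Alternatives were the deposited normalized table, no background correction, median scaling, no filter, a filter at the 60th percentile on 6 arrays, a trended and robust spread, array weights, a fit of the compared arrays alone, a log2 change of at least 1, the mean of the probes of a gene, and leaving out each array. Added after the data were seen were median scaling on probes above the 60th percentile on all arrays and fits with vehicle array 24 left out or kept as the lone vehicle array, correlations with separate arrays of the shared group, hepatocyte genes matched for PBS level to the male-biased genes, and the clock index without each array. Fits were tested on simulated data with 50 changed genes per size. For erlotinib 2 against vehicle they recovered 36%, 94%, 100% and 100% at log2 changes of 0.5, 1, 2 and 3, and for the interaction 14%, 72%, 98% and 100%. False calls numbered 6 and 12. Simulated genes varied independently and equally on every array, which real arrays need not do, so these shares may not carry over. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6. No array and no column was left out.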

Results

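Gene expression was measured in non-tumour liver of male Wistar rats that had received weekly intraperitoneal injections of diethylnitrosamine (DEN), a hepatocarcinogen that is activated by cytochrome P450 enzymes in hepatocytes, or of phosphate-buffered saline (PBS). Total RNA from 21 livers was hybridised to Illumina bead arrays, 1 array per liver and 3 arrays in each of 7 groups. At the time point labelled week 12 the groups were PBS, DEN at 50 mg/kg (DEN 50) and DEN at 100 mg/kg (DEN 100). At the time point labelled week 18 they were PBS and 3 groups of DEN 50 rats, which received vehicle, erlotinib at 0.5 mg/kg (erlotinib 0.5) or erlotinib at 2 mg/kg (erlotinib 2) in weeks 13 to 18. Erlotinib is an inhibitor of the tyrosine kinase of the epidermal growth factor receptor (EGFR). The labels call the DEN livers cirrhotic and state that killing followed a washout of 1 week.

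The number in each label was read as a separate rat, although nothing in the labels says so outright, so p-values measure the spread between these samples. The number of arrays limits the precision. The doses of erlotinib were used in 2 separate studies whose vehicle rats were combined, and the labels do not say which vehicle rat belonged to which study. A difference between the erlotinib doses can therefore not be told apart from a difference between the studies. The PBS rats at week 18 had no vehicle injections. Values below are log2 changes ± SE from limma with 3 arrays per group unless stated otherwise, and adjusted p-values are Benjamini-Hochberg values from limma's moderated test over 19335 features.

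The first principal component carried 50.7% of the variance and placed all 6 PBS arrays at one end and the 3 DEN 100 arrays at the other, with the DEN 50 arrays between them. Components 2 and 3 carried 10.7% and 4.9%. Vehicle array 24 lay apart from the other vehicle arrays on component 3, at 34.5 against -1.1 and -0.3.

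**Figure D1:**
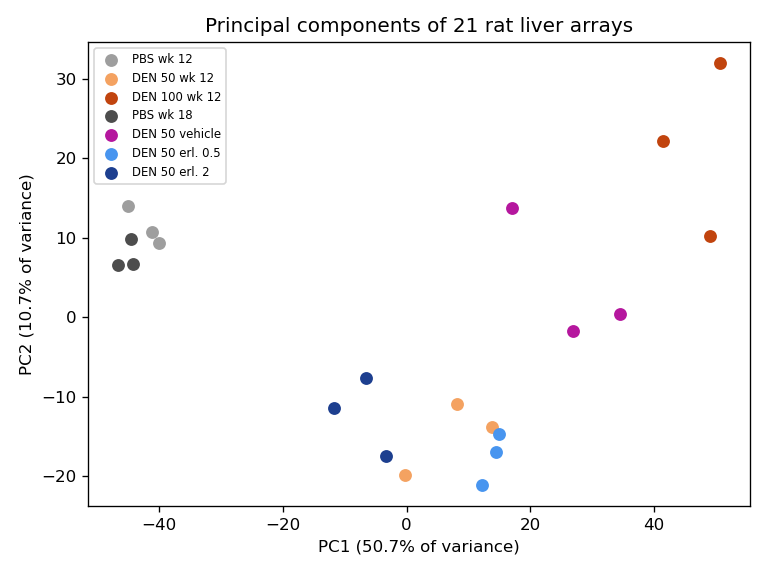
Scores of the 21 arrays on the first principal component (x axis, 50.7% of the variance) and the second (y axis, 10.7%), 1 point per array and 1 colour per group. The erlotinib 2 arrays lie at -11.7 to -3.3 on the first component, between the PBS arrays (-46.6 to -40) and the vehicle arrays (17.1 to 34.5).

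The comparison of DEN 50 with PBS at week 12 asked how the liver had changed before erlotinib began. Markers of preneoplastic rat liver were among the most strongly raised genes. Gstp1, the placental glutathione S-transferase that marks preneoplastic rat hepatocytes, rose by 7.06 ± 0.31 (adjusted p = 4.8e-12), Serpinb1a by 5.88 ± 0.44 and the aldose reductase family member Akr1b8 by 5.78 ± 0.55. Of 17 measured members of the preneoplastic and oncofetal list 12 rose and none fell, among them the basolateral efflux pump gene Abcc3 by 3.63 ± 0.19. The oncofetal proteoglycan Gpc3 rose by 2.97 ± 0.16, whereas alpha-fetoprotein, Afp, had a change of -0.17 ± 0.22 (adjusted p = 0.74). Of 22 genes of the NRF2 and xenobiotic stress list 18 rose and none fell, with the glutathione S-transferase Gsta3 up by 4.53 ± 0.25, the quinone reductase Nqo1 up by 3.86 ± 0.29 and Akr7a3 up by 3.52 ± 0.29. Gene families such as the glutathione S-transferases have close paralogs that may share probes, so the identity of a single member is uncertain.

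Genes of the matrix, of dividing cells and of biliary cells were also higher in DEN 50 livers at week 12. Of the lists in this paragraph, matrix alone kept its camera call with an estimated correlation. In the fibrillar collagen and matrix list 15 of 29 genes rose and 2 fell (17 and 2 adjusted over the list alone). Col1a2 rose by 2.04 ± 0.25, Mgp by 1.96 ± 0.30, Col4a1 by 1.79 ± 0.28, Col1a1 by 1.37 ± 0.14 and Timp1, an inhibitor of matrix metalloproteinases, by 1.23 ± 0.21. Lox, which crosslinks collagen, went the other way at -2.03 ± 0.27. Tgfb1 rose by 0.87 ± 0.21, the matricellular gene Ccn2 by 3.30 ± 0.39, and the myofibroblast genes Tagln and Vim by 2.13 ± 0.20 and 1.87 ± 0.21. Of 35 cell cycle and DNA replication genes 19 rose and none fell (26 adjusted over the list alone), with Cdk1 up by 2.50 ± 0.25, Ccnb2 by 2.39 ± 0.26, Cdkn3 by 2.31 ± 0.21 and Ccnd1 by 1.68 ± 0.38. Of 15 cholangiocyte and progenitor markers 8 rose and 2 fell, with Cd24 up by 2.75 ± 0.32, Epcam by 2.53 ± 0.32 and the biliary keratin Krt19 by 2.18 ± 0.42. Of 8 MHC class II genes 5 rose, among them RT1-DMb by 1.87 ± 0.29 and Cd74 by 1.58 ± 0.31. Scores of other cell types were higher without overlap, by 0.66 for mesothelium and capsule, which includes Krt19, 0.38 for macrophages, 0.33 for mast cells, 0.32 for neutrophils and 0.25 for endothelium, and the red blood cell score was lower by -0.53 (exact two-sided permutation p = 0.1 each). The medians of the mast cell, neutrophil and endothelium lists went from 0.33 to -0.17, from 0.02 to -0.54 and from 0.20 to -0.15 with bright-probe scaling. Of the 6 mesothelium and capsule genes 1 passed, Krt19 itself. This list therefore cannot say whether part of the rise of Krt19 came from capsule.

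Transcripts of some hepatocyte genes were lower in the same comparison, although the calls of the lists below were lost with an estimated correlation. In the male-biased list 5 of 13 genes fell and none rose (9 adjusted over the list alone); the odorant-binding protein Obp3 changed by -6.12 ± 0.42 and the male-specific cytochrome Cyp2c11 by -4.14 ± 0.85. The major urinary protein gene Mup4l3 changed by -6.46 ± 0.66, Stac3 by -5.81 ± 0.37 and the aldehyde oxidase Aox3 by -3.98 ± 0.22, while the female-specific Cyp2c12 rose by 2.15 ± 0.36. Of 30 cytochrome P450 and drug metabolism genes 8 fell and 3 rose, with Cyp4a2 at -2.64 ± 0.60 and Cyp3a9 at -2.42 ± 0.39. Of 26 urea cycle and amino acid catabolism genes 10 fell and none rose, with the ornithine aminotransferase Oat at -2.50 ± 0.30 and the glycine methyltransferase Gnmt at -1.76 ± 0.39. Egf, the ligand of EGFR, changed by -1.30 ± 0.15 and Egfr itself by -1.16 ± 0.25. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and the desaturase Scd rose by 1.88 ± 0.57 and 1.87 ± 0.48. The PBS arrays of week 12 spread widely for both, with SDs of 1.72 and 1.43. The DEN 50 means of 12.26 and 14.35 lay close to those of PBS at week 18, 12.06 and 14.59. Alb, which encodes albumin, had a change of -0.02 ± 0.17 (adjusted p = 0.98). Its level of 15.05 in PBS livers was near the top of the intensity scale, so a change of Alb could be missed here and in the comparisons below. Among p53 targets Mdm2 rose by 1.11 ± 0.20 and Ccng1 by 0.94 ± 0.23, and Cdkn1a had a change of 0.37 ± 0.14 (adjusted p = 0.12).

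By limma 2108 features changed between DEN 50 and PBS at week 12, 1115 up and 993 down (52.9% up). The up share was 89.7% of 1377 calls with arrays scaled to their medians, and 35.0% of 1312 calls with scaling on bright probes, which moved the median of all genes by -0.50 log2. The genes said here to have risen or fallen changed by more than that shift, whereas Cdkn1a, Afp and Alb did not, and Cdkn1a went to -0.17 with this scaling. Akr1b8, Gpc3, Cdk1, Cdkn3 and Col1a1 lay near background in PBS livers and Aox3 in DEN 50 livers, so their changes are lower limits. With a preset inter-gene correlation of 0.01, limma's camera called 23 of 35 lists, 15 up and 8 down, and 3 lists held with an estimated correlation: matrix (adjusted p = 0.04), preneoplastic and oncofetal (adjusted p = 0.0021) and NRF2 (adjusted p = 0.01). The other camera calls on lists described here were lost, with adjusted p = 0.065 for cell cycle, 0.24 for cholangiocyte and progenitor, 0.067 for MHC class II, 0.055 for male-biased, 0.16 for cytochrome P450, 0.16 for urea cycle and 0.27 for p53 targets with an estimated correlation.

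DEN 100 was compared with PBS at week 12 to describe the higher dose. Akr1b8 rose by 7.06 ± 0.55, the beta-defensin Defb1 by 6.89 ± 0.36, Gstp1 by 6.72 ± 0.31 (adjusted p = 1.9e-12), Gsta3 by 5.01 ± 0.25 and Gpc3 by 4.30 ± 0.16. Of 17 preneoplastic and oncofetal genes 13 rose, and of 22 NRF2 genes 19 rose, with none falling in either list. Of 15 cholangiocyte and progenitor markers 11 rose and 2 fell, with Cd24 up by 4.36 ± 0.32 and Krt19 by 3.86 ± 0.42. In the p53 target and DNA damage list 10 of 19 genes rose and none fell, with Ccng1 up by 2.87 ± 0.23, Mdm2, the ubiquitin ligase of p53, by 2.23 ± 0.20, Phlda3 by 2.19 ± 0.23 and the cell cycle inhibitor Cdkn1a by 1.29 ± 0.14. Of 29 matrix genes 17 rose and 3 fell, with Mgp up by 4.33 ± 0.30, Timp1 by 1.96 ± 0.21, Col1a2 by 1.56 ± 0.25 and Col1a1 by 0.89 ± 0.14. Of 35 cell cycle genes 22 rose and none fell (27 adjusted over the list alone), with Cdk1 up by 2.97 ± 0.25 and Rrm2 by 2.63 ± 0.29. Scores of other cell types were higher without overlap, by 1.24 for MHC class II, 1.09 for mesothelium and capsule, which includes Krt19, 0.81 for mast cells, 0.53 for neutrophils, 0.43 for endothelium and 0.12 for pancreatic acinar cells (exact two-sided permutation p = 0.1 each). The medians of the neutrophil and pancreatic acinar lists went from 0.04 to -0.16 and from 0.03 to -0.25 with bright-probe scaling.

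The hepatocyte genes that were lower after DEN 100 covered more lists. Of 13 male-biased genes 12 fell and 1 rose, with Mup4 at -8.35 ± 0.88, Mup5 at -7.99 ± 0.84 and Cyp2c11, which ended near background, at -8.37 ± 0.85. The muscle and liver carbonic anhydrase Car3 changed by -7.90 ± 0.46. Of 30 cytochrome P450 genes 20 fell and 1 rose, with Cyp3a2 at -7.46 ± 0.70, Cyp1a2 at -5.77 ± 0.44 and Cyp2e1, which activates DEN, at -2.75 ± 0.27. Of 17 bile acid synthesis and hepatobiliary transport genes 13 fell and 1 rose, with the uptake transporters Slco1b2 and Slc10a1 at -4.89 ± 0.29 and -4.35 ± 0.21, the bile acid ligase Slc27a5 at -4.52 ± 0.47, Baat at -3.67 ± 0.18 and Cyp7a1 at -2.33 ± 0.57. Of 16 lipogenesis genes 9 fell and 2 rose, with Thrsp at -4.00 ± 0.51 and Fads1 at -3.24 ± 0.23. Of 14 cholesterol synthesis genes 11 fell, among them Msmo1 at -2.76 ± 0.29. Of 24 hepatocyte secreted proteins 16 fell and 1 rose, with Igfals at -3.27 ± 0.14 and Apoa2 at -3.01 ± 0.30, while Alb had a change of -0.30 ± 0.17 (adjusted p = 0.26) on the brightest probe and of 0.38 (adjusted p = 0.043) on another bright probe, so its direction is not settled. Egf changed by -1.94 ± 0.15 and Egfr by -1.60 ± 0.25. The female-specific Cyp2c12 rose by 2.23 ± 0.36.

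Limma called 4114 features in DEN 100 against PBS, 2216 up and 1898 down (53.9% up), against 67.9% up of 2317 calls with median scaling. Bright-probe scaling moved the median of all genes by -0.21. Camera called 25 lists, 14 up and 11 down. With an estimated correlation 9 held, among them preneoplastic and oncofetal (adjusted p = 0.0041), p53 targets (0.047), secreted proteins (0.049), cytochrome P450 (0.0042), male-biased (0.0059), bile acid (0.00048) and cholesterol synthesis (0.049), and NRF2 held at 0.028. The calls of the matrix list (adjusted p = 0.064 with an estimated correlation), cell cycle (0.064), cholangiocyte and progenitor (0.076) and lipogenesis (0.067) were lost.

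In the direct comparison of the doses at week 12, hepatocyte genes were lower in DEN 100 than in DEN 50. Mup5 changed by -7.59 ± 0.84, Car3 by -5.43 ± 0.46, Cyp3a2 by -5.40 ± 0.70, Cyp7a1 by -4.22 ± 0.57, Slco1b2 by -3.69 ± 0.29 and Cyp2e1 by -2.56 ± 0.27. Of 30 cytochrome P450 genes 17 fell and none rose, and of 17 bile acid genes 10 fell and none rose. Of 16 lipogenesis genes 6 fell and 1 rose, with Thrsp at -3.94 ± 0.51. The thioesterase Acot1 rose by 3.29 ± 0.55, Ms4a4a by 3.10 ± 0.23, lipoprotein lipase, Lpl, by 2.75 ± 0.26 and Mgp by 2.37 ± 0.30. Of 19 p53 targets 5 rose and none fell, with Cdkn1a up by 0.92 ± 0.14. The matrix list moved in both directions, 5 up and 4 down, with Timp1 up by 0.73 ± 0.21, Col1a1 at -0.48 ± 0.14 (adjusted p = 0.036), Col1a2 at -0.48 ± 0.25 (adjusted p = 0.32) and a camera adjusted p of 0.99 for the list. Markers of other cells were higher in DEN 100 alongside: 6 of 15 cholangiocyte and progenitor genes, 4 of 11 mast cell genes and 3 of 10 red blood cell genes rose and none fell, with Hbb up by 2.34 ± 0.51 (camera adjusted p = 0.18 for each list with an estimated correlation). Scores of mesothelium and capsule and of pancreatic acinar cells were higher by 0.43 and 0.22 without overlap, which chance gives in 10% of cases for 3 against 3 arrays, and did not pass camera (adjusted p = 0.48 and 0.56). The red blood cell score was 7.82 in DEN 50, 8.60 in DEN 100 and 8.35 in PBS at week 12, so DEN 50 was the lower group. Gstp1 had a change of -0.35 ± 0.31 (adjusted p = 0.66) between the doses, Gpc3 rose by 1.33 ± 0.16 and Krt19 by 1.68 ± 0.42, and Egf changed by -0.64 ± 0.15.

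Between the doses 1815 features changed by limma, 982 up and 833 down (54.1% up), against 20% up of 676 calls with median scaling. With bright-probe scaling 945 features were called and the median of all genes moved by 0.30. Without the DEN 100 array DEN_113 the count was 1201. Camera called 18 lists, 5 up and 13 down, and 8 held with an estimated correlation, including p53 targets (adjusted p = 0.037), cytochrome P450 (0.0012), bile acid (3.2e-05) and lipogenesis (0.017). Both DEN groups shared the same PBS arrays. Their changes against PBS correlated across genes with r = 0.79, against a mean of 0.49 (range -0.13 to 0.73) in simulations with unchanged groups and the same shared arrays, and the covariance was 0.225 against a simulated 0.0169. Genes are not independent replicates. Of genes up in both, 937 were found where independent lists would give 127.8, and of genes down in both, 770 against 97.5. With separate PBS arrays in each comparison, 1 against the other 2 in all 6 ways, a check added after the data were seen, r was 0.64 to 0.70.

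At week 18, DEN 50 livers with vehicle injections were compared with PBS livers, which describes the disease state against which erlotinib was tested. Gstp1 rose by 7.02 ± 0.31 (adjusted p = 2.7e-12), Serpinb1a by 6.10 ± 0.44, Akr1b8 by 5.97 ± 0.55, Defb1 by 5.78 ± 0.36 and Gpc3 by 3.66 ± 0.16. Of 17 preneoplastic and oncofetal genes 12 rose and none fell, and of 22 NRF2 genes 19 rose and none fell, with Nqo1 up by 3.94 ± 0.29 and Abcc3 by 3.26 ± 0.19. Afp had a change of 0.18 ± 0.22 (adjusted p = 0.68). Of 29 matrix genes 21 rose and 1 fell (22 and 1 adjusted over the list alone), with Mgp up by 3.35 ± 0.30, Col1a2 by 2.79 ± 0.25, the proteoglycan decorin, Dcn, by 2.76 ± 0.31, Timp1 by 2.44 ± 0.21 and Col1a1 by 1.14 ± 0.14. Of 11 TGF-beta signalling genes 8 rose and 2 fell, with Pmepa1 up by 1.71 ± 0.20 and Tgfb1 by 1.05 ± 0.21. The myofibroblast genes Vim and Tagln rose by 3.07 ± 0.21 and 2.87 ± 0.20. Of 35 cell cycle genes 21 rose and none fell (26 adjusted over the list alone), with Cdk1 up by 2.67 ± 0.25 and Ccnb2 by 2.13 ± 0.26.

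Markers of biliary and immune cells moved with these groups, although of their lists MHC class II alone kept its camera call with an estimated correlation. Of 15 cholangiocyte and progenitor markers 9 rose and 2 fell, with Cd24 up by 3.66 ± 0.32, Krt19 by 3.05 ± 0.42, osteopontin, Spp1, by 2.66 ± 0.41 and Epcam by 2.36 ± 0.32. Of 18 macrophage markers 13 rose and 1 fell, with the complement genes C1qb and C1qc up by 1.83 ± 0.26 and 1.82 ± 0.27. Of 8 MHC class II genes 7 rose, with RT1-Db1 up by 2.53 ± 0.31 and RT1-Da by 2.46 ± 0.29. Of 27 cytokines and chemokines 11 rose and 1 fell, with Cxcl16 up by 2.62 ± 0.21 and the lymphoid chemokine Ccl19 by 2.53 ± 0.31. The PBS liver at week 18 also expressed 10 of the 15 cholangiocyte and progenitor markers, 16 of the 18 macrophage markers and 6 of the 8 MHC class II genes above the array median, so these lists do not count cells. Among lists of cells from outside the liver lobule, 3 of 6 mesothelium and capsule genes rose, with mesothelin, Msln, up by 1.33 ± 0.31 and Krt19, which is also a biliary marker, among them. The score of this list was higher than with PBS by 0.97, without overlap (exact two-sided permutation p = 0.1), and limma's camera gave adjusted p = 0.022, and adjusted p = 0.054 with an estimated correlation. Part of the rise of Krt19 could therefore come from capsule. Pancreatic acinar cells (camera adjusted p = 1), skeletal muscle and adipose tissue (0.67) and red blood cells (0.73) did not pass.

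Of 13 male-biased genes 12 fell at week 18 and none rose, with Cyp2c11 at -6.67 ± 0.85, Obp3 at -6.65 ± 0.42 and Cyp3a2 at -4.35 ± 0.70, and Mup4l3 changed by -7.15 ± 0.66. The female-specific Cyp2c12 rose by 4.60 ± 0.36. Of 30 cytochrome P450 genes 19 fell and 3 rose, with Cyp3a9 at -4.10 ± 0.39 and Cyp2e1 at -1.02 ± 0.27. Of 26 urea cycle and amino acid genes 19 fell and none rose, with Oat at -2.53 ± 0.30 and Gnmt at -2.46 ± 0.39. Of 17 bile acid genes 9 fell and 1 rose, with Slc27a5 at -2.53 ± 0.47, Slco1b2 at -2.43 ± 0.29 and Slc10a1 at -2.29 ± 0.21. Of 16 lipogenesis genes 9 fell and 1 rose, with Scd at -3.07 ± 0.48 and the citrate lyase Acly at -2.15 ± 0.23, and the liver pyruvate kinase Pklr changed by -3.10 ± 0.34. Egf changed by -1.87 ± 0.15 and Egfr by -1.28 ± 0.25, and Alb had a change of 0.06 ± 0.17 (adjusted p = 0.87).

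**Figure D2:**
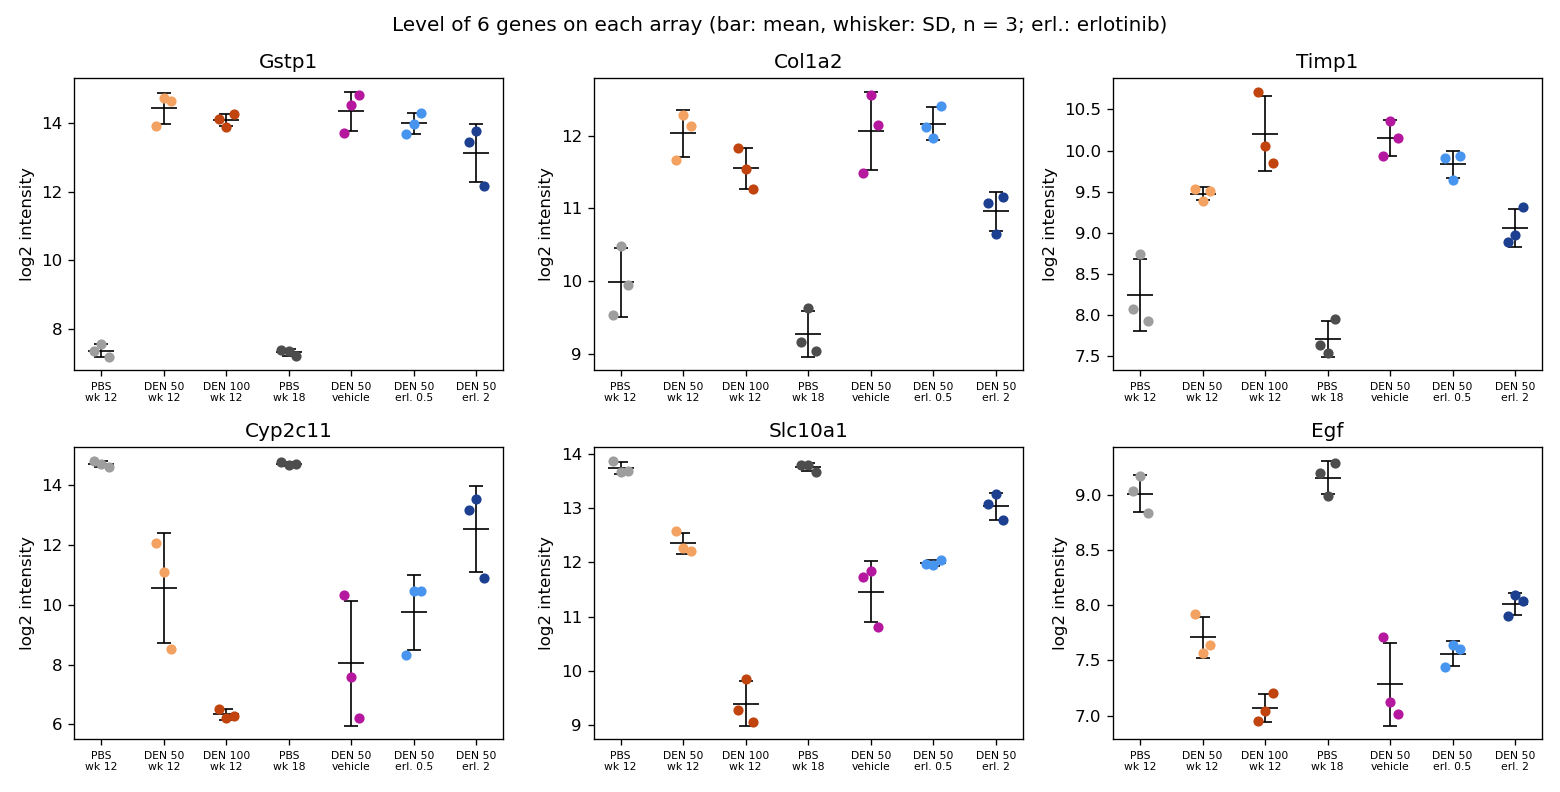
Normalized log2 intensity (y axis) of Gstp1, Col1a2, Timp1, Cyp2c11, Slc10a1 and Egf on each of the 21 arrays, by group (x axis), with the mean as a bar and the SD as whiskers (n = 3). Gstp1 was higher in every DEN group than in PBS, and in erlotinib 2 livers Col1a2 was lower and Slc10a1 higher than with vehicle, by -1.10 and 1.57 log2.

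Limma called 3528 features between DEN 50 with vehicle and PBS, 1839 up and 1689 down (52.1% up). The up share was 79.5% of 1964 calls with median scaling and 41.2% of 1944 calls with bright-probe scaling, which moved the median of all genes by -0.37. Camera called 25 lists, 15 up and 10 down, and 9 held with an estimated correlation: matrix (adjusted p = 0.0096), preneoplastic and oncofetal (0.008), NRF2 (0.018), MHC class II (0.028), cytochrome P450 (0.034), male-biased (0.013), bile acid (0.0096), urea cycle (0.044) and lipogenesis (0.024). Cell cycle, macrophage and TGF-beta signalling lost their calls, each with adjusted p = 0.052 with an estimated correlation, as did cholangiocyte and progenitor (adjusted p = 0.089) and cytokines and chemokines (0.12). The DEN 50 changes at weeks 12 and 18, which share no arrays, correlated across genes with r = 0.76, against a simulated mean of -0.04 (range -0.48 to 0.53), and 864 genes were up and 579 down at both times.

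Erlotinib 2 was compared with vehicle at week 18 to ask whether EGFR inhibition altered the DEN-treated liver. Genes of the matrix were lower in erlotinib 2 livers. Of 29 matrix genes 13 fell and none rose (17 adjusted over the list alone), with Mgp at -2.25 ± 0.30 (adjusted p = 0.00013), Dcn at -1.36 ± 0.31, the lysyl oxidase homolog Loxl1 at -1.34 ± 0.24, Col3a1 at -1.26 ± 0.31, Col1a2 at -1.10 ± 0.25, Timp1 at -1.09 ± 0.21 and Col1a1 at -0.68 ± 0.14. Of 15 stellate cell and myofibroblast genes 2 fell and none rose, Tagln at -1.83 ± 0.20 and Vim at -1.55 ± 0.21 (camera adjusted p = 0.0095, and adjusted p = 0.098 with an estimated correlation). Of 11 TGF-beta signalling genes 4 fell and 1 rose, with Pmepa1 at -1.30 ± 0.20 and Ltbp1 at -0.95 ± 0.15, whereas Tgfb1 had a change of -0.23 ± 0.21 (adjusted p = 0.70). Ccn2 changed by -1.99 ± 0.39. The matrix score, the mean log2 intensity of the list, was 8.13 ± 0.11 (SD, n = 3) with erlotinib 2, 8.71 ± 0.15 with vehicle and 7.60 ± 0.06 with PBS, and no erlotinib 2 array overlapped a vehicle array (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow).

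Some biliary and preneoplastic markers were also lower, although the calls of both lists were lost with an estimated correlation. Of 15 cholangiocyte and progenitor markers 6 fell and none rose, with Tspan8 at -1.79 ± 0.24, Spp1 at -1.62 ± 0.41, Cd24 at -1.50 ± 0.32 and Epcam at -1.32 ± 0.32, while Krt19 had a change of -1.45 ± 0.42 (adjusted p = 0.059). Of 17 preneoplastic and oncofetal genes 3 fell and none rose, with Gpc3 at -1.84 ± 0.16 and Gstp1 at -1.21 ± 0.31. The calcium-binding protein S100a6 changed by -2.05 ± 0.16. Of 27 cytokines and chemokines, a list whose call was also lost with an estimated correlation, 4 fell, with Cxcl16 at -1.42 ± 0.21, Ccl21 at -1.32 ± 0.23 and Ccl19 at -1.29 ± 0.31. The mast cell protease Cpa3 changed by -1.22 ± 0.27, and the macrophage receptor Marco rose by 1.26 ± 0.20. Scores of other cell types were lower without overlap, by -0.56 for MHC class II, -0.55 for mesothelium and capsule, -0.53 for mast cells, -0.31 for endothelium and -0.20 for pancreatic acinar cells (exact two-sided permutation p = 0.1 each). Mesothelin, Msln, changed by -1.11 ± 0.31 (adjusted p = 0.048), so a smaller share of capsule in the erlotinib 2 samples stays possible for Krt19 and for part of the matrix genes. None of the 35 cell cycle genes passed in either direction; their median change was -0.01, camera gave an adjusted p of 0.34, Pcna had a change of -0.61 ± 0.20 (adjusted p = 0.091) and Ccnd1 of -0.08 ± 0.38 (adjusted p = 0.97).

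Transcripts of part of the hepatocyte genes were higher in erlotinib 2 livers than with vehicle. Of 13 male-biased genes 7 rose and none fell (10 adjusted over the list alone), with Mup4 up by 4.69 ± 0.88, Cyp2c11 by 4.50 ± 0.85 and Cyp3a2 by 3.72 ± 0.70. The male-biased score spread widely over the vehicle arrays, at 10.23 ± 1.10 (SD, n = 3) against 12.24 ± 0.31 with erlotinib 2. Obp3 rose by 3.20 ± 0.42 and Car3 by 3.14 ± 0.46. Of 30 cytochrome P450 genes 12 rose and none fell, with Cyp3a18 up by 2.40 ± 0.34. Of 17 bile acid genes 6 rose and none fell, with Slc27a5 up by 2.07 ± 0.47, Slc10a1 by 1.57 ± 0.21 and Slco1b2 by 1.49 ± 0.29. Of 16 lipogenesis genes 4 rose, with Scd up by 1.82 ± 0.48 and Fads1 by 1.42 ± 0.23, and of 14 cholesterol synthesis genes 5 rose (12 adjusted over the list alone), with Fdps up by 1.12 ± 0.22 and Cyp51 by 1.01 ± 0.20. Of 24 secreted proteins 8 rose, with Apoa2 up by 1.65 ± 0.30 and Igfals by 1.27 ± 0.14, and the ketone body enzyme Bdh1 rose by 1.22 ± 0.14. Egf rose by 0.72 ± 0.15, and Egfr had a change of 0.71 ± 0.25 (adjusted p = 0.13). Of 23 EGFR-ERK response genes 1 fell, the ERK pathway inhibitor Spred1 at -0.74 ± 0.20 (adjusted p = 0.038), and none rose (camera adjusted p = 0.90). Per the labels killing followed a washout of 1 week, so this list does not describe signalling during dosing.

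**Figure D3:**
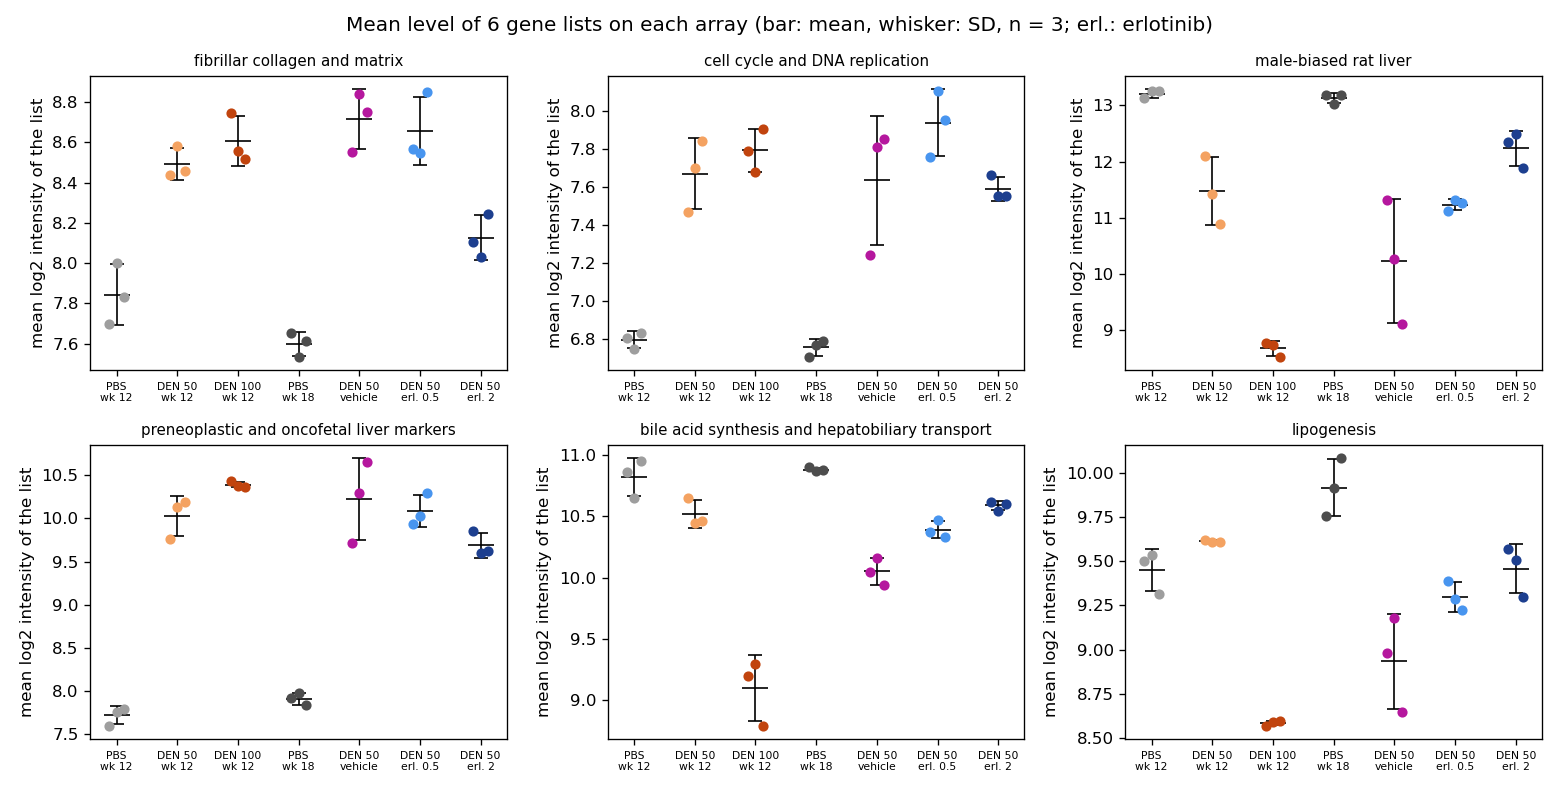
Mean log2 intensity of 6 gene lists (y axis) on each of the 21 arrays, by group (x axis), with the group mean as a bar and the SD as whiskers (n = 3). In erlotinib 2 livers the matrix score was 8.13 against 8.71 with vehicle, while the cell cycle score was 7.59 against 7.64, with an SD of 0.34 over the vehicle arrays.

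Limma called 780 features between erlotinib 2 and vehicle, 371 up and 409 down (47.6% up), against 64.8% up of 125 calls with median scaling, of which 123 were among the 780, and 61.7% up of 337 calls with bright-probe scaling, all of them among the 780. The count was 333 without erlotinib 2 array 29, 496 without erlotinib 2 array 31 and 467 without vehicle array 69. Camera called 25 lists, 12 up and 13 down, and 6 held with an estimated correlation: matrix (adjusted p = 0.023), cytochrome P450 (0.023), male-biased (0.023), bile acid (0.012), lipogenesis (0.045) and cholesterol synthesis (0.049). The calls lost with an estimated correlation included preneoplastic and oncofetal (adjusted p = 0.056), TGF-beta signalling (0.056), cholangiocyte and progenitor (0.098), secreted proteins (0.098) and cytokines and chemokines (0.31).

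In erlotinib 0.5 livers fewer genes differed from vehicle. S100a6 changed by -1.25 ± 0.16 (adjusted p = 0.0026), Gpc3 by -1.07 ± 0.16, Rasl11b by -1.39 ± 0.26 and the annexin Anxa1 by -0.98 ± 0.19. Fads1 rose by 1.44 ± 0.23, the aldo-keto reductase Akr1c2 by 1.53 ± 0.30, the steroid dehydrogenase Hsd3b5 by 1.25 ± 0.22, the deiodinase Dio1 by 1.18 ± 0.20, Ndrg2 by 1.05 ± 0.18, Marco by 1.03 ± 0.20, the organic anion transporter Slc22a7 by 1.02 ± 0.20 and Bdh1 by 0.71 ± 0.14. None of the 29 matrix genes passed, with Col1a1 at 0.36 ± 0.14 (adjusted p = 0.32) and Col1a2 at 0.10 ± 0.25 (adjusted p = 0.95). Gstp1 had a change of -0.36 ± 0.31 (adjusted p = 0.76), Ccnd1 of 1.37 ± 0.38 (adjusted p = 0.15) and Egfr of 0.15 ± 0.25 (adjusted p = 0.91). Of 17 bile acid genes 1 rose, Slc22a7, and 7 rose and 1 fell when adjusted over the list alone. None of 14 cholesterol synthesis genes passed over all genes and 8 rose adjusted over the list alone.

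Limma called 27 features between erlotinib 0.5 and vehicle, 20 up and 7 down, of which 26 were also called with erlotinib 2, 19 up and 7 down in both, where independent lists would give 0.4 and 0.1. Both comparisons use the same vehicle arrays, so part of this overlap may come from them; r was 0.71, within the range of 0.06 to 0.72 simulated without effects. No feature was called by limma with median scaling (957 at an unadjusted p under 0.05) or with bright-probe scaling (1057). The count was 139 with array weights, 15 with the deposited normalized values, 2 in a fit of the compared arrays alone and 776 with vehicle array 24 as the lone vehicle array. It was 3 without erlotinib 0.5 array 73, 8 without array 74 and 8 without vehicle array 69. Camera called 11 lists, 9 up and 2 down (17 without vehicle array 24), and the bile acid list alone held with an estimated correlation (adjusted p = 0.043). The calls of cell cycle and cholesterol synthesis were lost, with adjusted p = 0.38 and 0.21 with an estimated correlation.

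The doses of erlotinib were compared directly, which also compares the studies they came from. Col1a1 changed by -1.04 ± 0.14 (adjusted p = 0.0034) in erlotinib 2 relative to erlotinib 0.5, Tagln by -1.51 ± 0.20, Loxl1 by -1.37 ± 0.24, Vim by -1.17 ± 0.21, the glutathione peroxidase Gpx3 by -1.38 ± 0.20 and the growth factor gene Pdgfa by -0.83 ± 0.15. Mup4l3 rose by 3.83 ± 0.66, Obp3 by 2.50 ± 0.42, Stac3 by 1.96 ± 0.37 and the growth hormone receptor, Ghr, by 0.83 ± 0.16. Of 29 matrix genes 2 fell and none rose (15 adjusted over the list alone), and Col1a2, Gpc3 and Ccnd1 had changes of -1.20 ± 0.25 (adjusted p = 0.068), -0.77 ± 0.16 (0.057) and -1.45 ± 0.38 (0.14). Limma called 15 features, 7 up and 8 down (46.7% up). Up calls were 1 of 4 with the deposited normalized table, 1 of 5 without background correction, 92 of 194 with array weights, 0 of 1 with median scaling and 1 of 3 with bright-probe scaling, which moved the median of all genes by 0.11. A fit of the compared arrays alone called 273. The count was 1 without erlotinib 2 array 29, 3 without array 27, 29 without array 31, 5 without erlotinib 0.5 array 73 and 3 without array 74. Camera called 21 lists, 9 up and 12 down, of which matrix held with an estimated correlation (adjusted p = 0.017).

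With both doses combined against vehicle, Gpc3 changed by -1.46 ± 0.14, S100a6 by -1.65 ± 0.14, Rasl11b by -1.67 ± 0.22 and Timp1 by -0.71 ± 0.18, whereas Col1a1 had a change of -0.16 ± 0.12 (adjusted p = 0.63). Cyp3a18 rose by 1.97 ± 0.29, Akr1c2 by 1.84 ± 0.26, Hsd3b5 by 1.67 ± 0.19 and Egf by 0.50 ± 0.13. Limma called 582 features, 300 up and 282 down (51.5% up), against 78.3% up of 69 calls with median scaling and 70.6% up of 153 with bright-probe scaling. The count was 311 without vehicle array 69, 334 without vehicle array 24, 332 without erlotinib 0.5 array 73 and 366 without erlotinib 2 array 29. Camera called 26 lists, 13 up and 13 down, and 3 held with an estimated correlation: cytochrome P450 (adjusted p = 0.046), male-biased (0.046) and bile acid (0.012).

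Whether erlotinib moved the genes changed by DEN back toward PBS was asked with the genes called in DEN 50 against PBS at week 12, which were chosen on arrays that enter no erlotinib comparison. In erlotinib 2 against vehicle, the 1115 raised genes had a mean change of -0.36 and the 993 lowered genes of 0.33, and 78.9% and 75.9% of them moved toward PBS. Limma called 242 of the raised genes toward PBS and 2 away, and 178 of the lowered genes toward PBS and 3 away (camera p = 0.0015 for each list with an estimated correlation). Gpc3, Col1a2 and Timp1 were among the raised genes and Obp3 and Cyp2c11 among the lowered. In erlotinib 0.5 the means were -0.02 and 0.01 (camera p = 0.83 and 0.72 with an estimated correlation). With median scaling they were 0.03 and 0.28 in erlotinib 0.5 and -0.37 and 0.86 in erlotinib 2, so a shift of the lowered genes with erlotinib 0.5 depends on the scaling. In the direct comparison of the doses the means were -0.34 and 0.33 (camera p = 0.00015 and 3.7e-05 with an estimated correlation). For both doses together they were -0.19 and 0.17 (camera p = 0.031 and 0.054 with an estimated correlation).

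A score per array, the mean of the raised genes minus that of the lowered genes relative to PBS at week 18, was 1.84 ± 0.28 (SD, n = 3) with vehicle, 1.82 ± 0.03 with erlotinib 0.5, 1.16 ± 0.14 with erlotinib 2 and 1.72 ± 0.12 in DEN 50 at week 12. The erlotinib 2 score was below vehicle by -0.69, or 37.3% of the difference between vehicle and PBS, with no overlap of arrays (exact two-sided permutation p = 0.1, the smallest possible). With the genes called in DEN 100 against PBS at week 12, the erlotinib 0.5 lists also moved toward PBS, with means of -0.11 and 0.14 (camera p = 0.025 and 0.012 with an estimated correlation), and the score was lower than with vehicle by -0.25 for erlotinib 0.5 and by -0.72 for erlotinib 2.

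**Figure D4:**
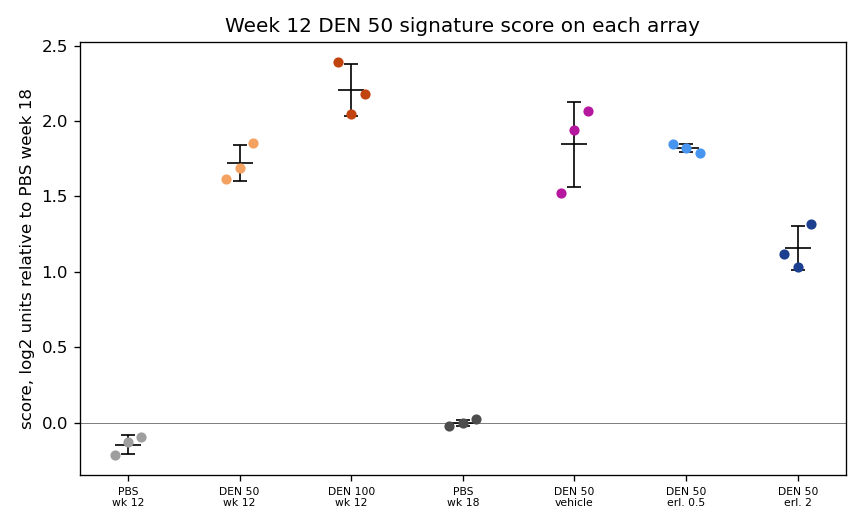
Score of the genes changed by DEN 50 at week 12 (y axis, log2 units relative to PBS at week 18) on each array by group (x axis), with the mean as a bar and the SD as whiskers (n = 3). The erlotinib 2 arrays (1.03 to 1.32) lie below all vehicle arrays (1.52 to 2.07).

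The week 18 DEN changes share the vehicle arrays with the erlotinib comparisons in opposite sign. Across genes, DEN 50 with vehicle against PBS and erlotinib 2 against vehicle correlated with r = -0.79, against a mean of -0.48 (range -0.81 to -0.03) in simulations without effects, and the covariance was -0.135 against a simulated -0.0157. Of the 780 features called with erlotinib 2, 748 were also called in DEN 50 with vehicle against PBS, 747 of them in the opposite direction. Genes up after DEN and down with erlotinib 2, such as Mgp and Tagln, numbered 395 where independent lists would give 38.9, and genes down and then up, such as Cyp2c11, numbered 352 against 32.4. For erlotinib 0.5, r was -0.46 against a simulated -0.48, with a covariance of -0.0606 against -0.016. The changes with both doses against their shared vehicle correlated with r = 0.71 against a simulated 0.49 (range 0.06 to 0.72), with a covariance of 0.0547 against 0.0162. With separate vehicle arrays in each comparison, 1 against the other 2 in all 6 ways, r was -0.68 to -0.40 for DEN and erlotinib 2, -0.45 to -0.02 for DEN and erlotinib 0.5 and 0.13 to 0.50 between the erlotinib doses, a check added after the data were seen. A lone array adds spread that lowers the size of r, and part of each excess over the simulations may come from the shared arrays. The week 12 DEN 50 changes, which share none, correlated with erlotinib 2 at r = -0.49 against a simulated 0 (range -0.49 to 0.53) and with erlotinib 0.5 at r = -0.07.

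**Figure D5:**
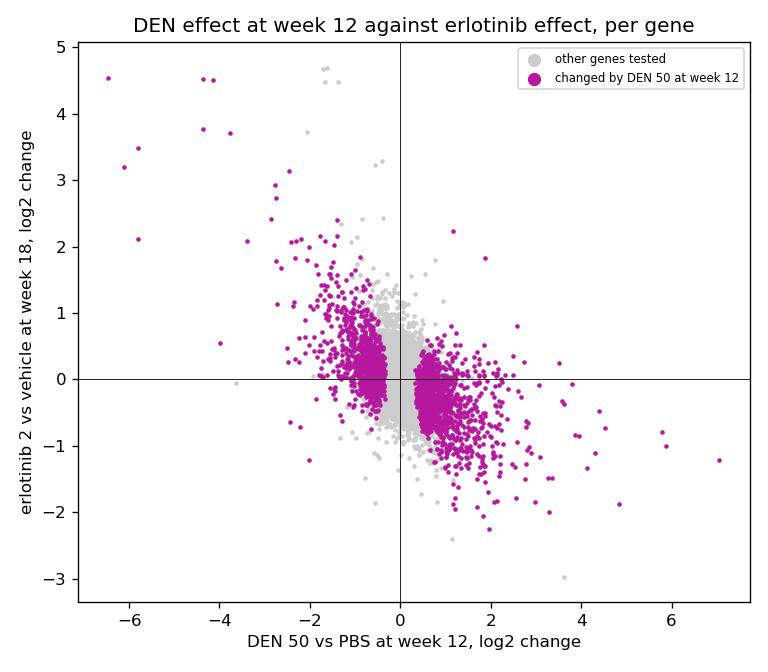
Log2 change in DEN 50 against PBS at week 12 (x axis) and in erlotinib 2 against vehicle at week 18 (y axis), 1 point per gene, with the genes called at week 12 in colour. Across genes r was -0.49, and 420 of 425 genes called in both comparisons had opposite signs.

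Against PBS at week 18, erlotinib 2 livers still carried preneoplastic markers, with Gstp1 up by 5.81 ± 0.31, Akr1b8 by 5.18 ± 0.55 and Gpc3 by 1.81 ± 0.16, and the female-specific Cyp2c12 was up by 3.64 ± 0.36. Of 17 preneoplastic and oncofetal genes 10 rose, of 22 NRF2 genes 13 rose, of 35 cell cycle genes 17 rose and of 29 matrix genes 11 rose and 1 fell, the latter Lox at -2.17 ± 0.27. Col1a2 rose by 1.68 ± 0.25, Timp1 by 1.35 ± 0.21 and Krt19 by 1.60 ± 0.42, and Col1a1 had a change of 0.46 ± 0.14 (adjusted p = 0.061). Stac3 changed by -4.20 ± 0.37, Obp3 by -3.45 ± 0.42 and Egf by -1.15 ± 0.15. Limma called 1097 features, 649 up and 448 down (59.2% up), against 86.2% up of 327 calls with median scaling. With bright-probe scaling 436 were called and the median of all genes moved by -0.29, and without erlotinib 2 array 31 the count was 599. Camera called 18 lists, 12 up and 6 down, and 4 held with an estimated correlation: matrix (adjusted p = 0.049), preneoplastic and oncofetal (0.0039), NRF2 (0.026) and cell cycle (0.049).

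In erlotinib 0.5 livers against PBS, Gstp1 rose by 6.67 ± 0.31, Akr1b8 by 5.96 ± 0.55 and Col1a2 by 2.89 ± 0.25, and Stac3 changed by -6.16 ± 0.37, Obp3 by -5.95 ± 0.42 and Egf by -1.59 ± 0.15. Of 29 matrix genes 19 rose and 1 fell, and of 35 cell cycle genes 30 rose and none fell. Limma called 2994 features, 1550 up and 1444 down (51.8% up), against 84.2% up of 1685 calls with median scaling and 36.2% up of 1771 with bright-probe scaling, which moved the median of all genes by -0.43. Camera called 22 lists, and 8 held with an estimated correlation, among them matrix (adjusted p = 0.0097) and cell cycle (0.028).

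PBS livers at weeks 12 and 18 were compared to describe time and age without DEN. The largest changes by limma's moderated statistic included the hepatocyte transcription factor Onecut1 at -2.47 ± 0.40 (adjusted p = 0.077), Ethe1 at 0.95 ± 0.19 (0.097) and Cyp2d4 at 0.87 ± 0.16 (0.079), and Col1a2 and Cyp7a1 had changes of -0.71 ± 0.25 and 1.68 ± 0.57. Limma called 0 features, with 1568 at an unadjusted p under 0.05. A fit with a trended and robust spread called 6 and a fit with array weights 2, and leaving out PBS array 7 or PBS_108 of week 12 gave 7 or 12. Camera called 7 lists, 3 up and 4 down, of which lipogenesis had the smallest p (adjusted p = 1.3e-05). Lipogenesis was higher at week 18 with a median of 0.36 and a score higher by 0.47 without overlap (exact two-sided permutation p = 0.1), and Scd had a change of 2.12 ± 0.48 (adjusted p = 0.21) and Pklr of 1.05 ± 0.34 (0.41). The count of lists was 2 without PBS array 110 of week 12, 4 without PBS array 8 of week 18 and 2 without PBS array 9, and none held with an estimated correlation (adjusted p = 0.093 for lipogenesis).

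Between weeks 12 and 18 of DEN 50, lipogenic genes were lower at the later time. Scd changed by -2.82 ± 0.48, Fads1 by -1.90 ± 0.23 (adjusted p = 0.00059), Fads2 by -1.81 ± 0.26, Acly by -1.34 ± 0.23 and Pklr by -1.80 ± 0.34. Slco1b2 changed by -1.38 ± 0.29, Akr1c2 by -1.50 ± 0.30 and the ammonia channel Rhbg by -1.42 ± 0.25. The protease inhibitor A2m rose by 2.36 ± 0.45, Dcn by 1.61 ± 0.31, Ms4a4a by 1.46 ± 0.23, S100a6 by 1.38 ± 0.16, Lpl by 1.16 ± 0.26 and Gpc3 by 0.82 ± 0.16, and Gstp1 had a change of -0.09 ± 0.31 (adjusted p = 0.96). Markers of other cells were higher at week 18: camera called matrix, cholangiocyte and progenitor, macrophage, lymphocyte, endothelium, red blood cell and mast cell lists up, none of which held with an estimated correlation (adjusted p = 0.085 to 0.41). Scores were higher by 0.73 for red blood cells, 0.37 for mast cells, 0.33 for endothelium, 0.30 for macrophages, 0.15 for pancreatic acinar cells and 0.13 for lymphocytes, each without overlap, and Hbb had a change of 2.18 ± 0.51 (adjusted p = 0.058). The later rats also had vehicle injections. Limma called 29 features up and 76 down (27.6% up), against 1 up of 13 calls with median scaling and 4 up of 6 with bright-probe scaling, which moved the median of all genes by 0.18. The count was 9, 57 and 42 without DEN 50 arrays 11, 14 and 51 of week 12, and 17 without vehicle array 69. Camera called 19 lists, 7 up and 12 down, and 4 lower lists held with an estimated correlation: cytochrome P450 (adjusted p = 0.043), bile acid (0.0061), lipogenesis (0.026) and cholesterol synthesis (0.043).

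The difference between the DEN 50 effects at the time points was tested as an interaction. The effect on Scd was lower at week 18 by -4.94 ± 0.67 (adjusted p = 0.0035), on Pklr by -2.85 ± 0.48, on Acly by -2.16 ± 0.33, on Fads2 by -2.00 ± 0.36 and on Fads1 by -1.98 ± 0.33. Part of this came from PBS livers, in which Scd had a change of 2.12 between the weeks, with an SD of 1.43 over the PBS arrays of week 12, and Pklr of 1.05, beside -2.82 and -1.80 in DEN 50. Of 16 lipogenesis genes 4 had a lower effect at week 18 and none a higher (9 adjusted over the list alone), with a median of -0.83. The kinase Pdk2, which inhibits pyruvate dehydrogenase, differed by -1.77 ± 0.25 and Ethe1 by -1.74 ± 0.27, the latter with a change of 0.95 ± 0.19 in PBS between the weeks (adjusted p = 0.097). The effect was higher at week 18 on Cyp2c12 by 2.45 ± 0.51, on Pmepa1 by 1.40 ± 0.29 and on the gap junction gene Gja1 by 1.31 ± 0.27, and Cyp7a1 had a difference of -3.10 ± 0.81 (adjusted p = 0.098). For Cyp2c12 most of the difference came from PBS livers, with a change of -1.85 ± 0.36 (adjusted p = 0.094) between the weeks beside 0.60 ± 0.36 in DEN 50, whereas Pmepa1 had -0.51 in PBS and 0.89 in DEN 50. Limma called 45 features, 10 up and 35 down, against 0 up of 3 calls with median scaling and 0 up of 7 with bright-probe scaling, which moved the median of all genes by 0.14. Array weights gave 98 calls, 31 up and 67 down, and a fit of the compared arrays alone 85. With vehicle array 24 as the lone vehicle array there were 436. The count was 11 without PBS array 110 of week 12, 17 and 27 without DEN 50 arrays 11 and 14, 16, 23 and 19 without PBS arrays 8, 9 and 18 of week 18, 26 without vehicle array 69 and 75 without vehicle array 59. Camera called 19 lists, 9 up and 10 down, of which lipogenesis held with an estimated correlation (adjusted p = 0.0094).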

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

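The effect of DEN 50 at week 18 minus that at week 12 was the result that called for a closer look, because the interaction was tested directly. The lipogenesis pattern was picked after its interaction was seen. The tests of clock genes other than Per2, of a lower hepatocyte share and of genes matched for brightness were chosen only after the result was seen. So was the leaving out of arrays for the clock index.

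For 45 genes the DEN 50 effect differed between the time points. The difference was -4.94 for Scd, -2.85 for Pklr, -2.16 for Acly, -1.98 for Fads1, -2.00 for Fads2, -1.77 for Pdk2 and -1.74 for Ethe1, and the median over the 16 lipogenesis genes was -0.83. Part of the difference came from PBS livers: between the weeks Scd had a change of 2.12 in PBS (adjusted p = 0.21 by limma) and -2.82 in DEN 50, Pklr of 1.05 and -1.80, and the lipogenesis list a median of 0.36 and -0.33. Ethe1 had a change of 0.95 in PBS (adjusted p = 0.097 by limma), a large part of its difference. The difference was 2.45 for Cyp2c12, 1.40 for Pmepa1, 1.31 for Gja1, 1.19 for Rbms1 and 0.93 for Srsf6. Most of it came from PBS livers for Cyp2c12, with -1.85 in PBS (adjusted p = 0.094) and 0.60 in DEN 50, and for Srsf6, with -0.70 (adjusted p = 0.089) and 0.23. Of 100 splits drawn from 200 that exchanged DEN and PBS labels within each week, 15 gave at least 45 genes and the highest other gave 4227, so chance was not excluded by this count. Exchanging labels in 1 week adds the DEN effect common to both weeks, which is a structure of the samples.

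Lipogenic genes such as Scd and Acly follow feeding and the hour of day, so the hour of killing was tested with an index of 7 day and 4 night clock genes: the DEN effect on it was 0.36 ± 0.32 at week 12 and -0.76 ± 0.32 at week 18, a difference of -1.12 ± 0.46, which a different hour of killing could give, although it was -0.87 without the week 12 array PBS_108 and -0.98 without week 18 PBS array 9, both below the size set in advance for this test, and the week 12 effect was 0.11 without PBS_108. PBS over time had an index of 0.61 ± 0.32 (0.36 without PBS_108) with a lipogenesis score higher by 0.47, whereas erlotinib 2 against vehicle had an index of -0.75 ± 0.32 with a score higher by 0.52 and Scd up by 1.82, so the index and these genes do not move together in every comparison. For the difference between the DEN effects no clock gene passed alone, the lowest adjusted p by limma being 0.14 for Usp2 (-2.37). The index drew mostly on Usp2, Per1 (-1.53) and Nr1d1 (-1.26). Other day genes lay between 0.03 (Per2) and -0.52 (Dbp), and the 4 night genes between 0.10 (Clock) and 0.34 (Nfil3). The hour stays open, since the labels give none and DEN or erlotinib may act on clock or lipogenic genes themselves. Vehicle array 24 was argued against as the cause: without it the lipogenesis median was -0.77, a ratio of 0.92. A biological change of lipogenesis with longer DEN exposure remains untested.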

How the results depend on the processing

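Scaling on bright probes and the fits on vehicle array 24 were chosen only after the result was seen. No paired analysis was possible because replicate numbers are not shared between groups. A block for the BeadChip was not run because no chip is given. With 3 arrays per group, a group left with 1 array pools its spread with the other groups and is assumed to vary like them. The cause of the changes between settings was not tested. For 274 called results of genes named in the text, 2502 values in other settings kept their sign and call, whatever their size. Another 238 kept the sign but lost the call and 0 reversed, and leaving out arrays gave 1512, 228 and 0. For 30 results not called, 273 values stayed so with the same sign, 14 became called and 13 reversed. Leaving out arrays gave 166, 9 and 14 for these.

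With a log2 change of at least 1 also required, the counts by limma were 651 for DEN 50 and 1481 for DEN 100 against PBS at week 12, 519 between the DEN doses, 1108 for DEN 50 with vehicle against PBS, 16 for erlotinib 0.5, 258 for erlotinib 2, 114 for both doses, 875 and 360 for erlotinib 0.5 and 2 against PBS, and 37 for DEN 50 over time.

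With median scaling the counts were, in the same order, 1377, 2317, 676, 1964, 0, 125, 69, 1685, 327 and 13, with 1 between the erlotinib doses and 3 for the interaction. For erlotinib 0.5, limma had 957 at an unadjusted p under 0.05. The matrix score after DEN at week 18 moved from 1.12 to 1.31 and the bile acid score from -0.83 to -0.65. Of the week 12 signature in erlotinib 0.5, the lowered genes moved from 0.01 to 0.28 and the raised genes from -0.02 to 0.03. Afp in DEN 50 at week 12 reversed to 0.34, and Alb to 0.05 in DEN 50 and 0.28 in DEN 100 at week 12 and -0.02 at week 18.

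With bright-probe scaling the counts were, in that order, 1312, 2409, 945, 1944, 0, 337, 153, 1771, 436 and 6, with 3 between the erlotinib doses and 7 for the interaction (for erlotinib 0.5, 1057 at an unadjusted p under 0.05). Cdkn1a in DEN 50 at week 12 reversed to -0.17, Alb to 0.07 in DEN 100 and -0.42 at week 18, and Ccnd1 with erlotinib 2 and Gstp1 in DEN 50 over time came to 0.00.

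With the deposited normalized values, 15 features were called for erlotinib 0.5, 4 between the erlotinib doses and 33 for DEN 50 over time; the matrix score was 0.92 and Alb at week 18 -0.07. Without background correction 5 were called between the erlotinib doses and 69 for DEN 50 over time, with a matrix score of 0.93. With array weights 139 were called for erlotinib 0.5, 194 between the erlotinib doses, 908 for both doses, 2 for PBS over time, 204 for DEN 50 over time and 98 for the interaction, and Col1a2 with erlotinib 0.5 reversed to -0.11. A trended and robust spread gave 26 between the erlotinib doses and 6 for PBS over time. Fits of the compared arrays alone gave 970 between the DEN doses, 2 for erlotinib 0.5, 273 between the erlotinib doses, 1659 for erlotinib 2 against PBS, 9 for DEN 50 over time and 85 for the interaction. The mean of probes put Alb at 0.04 in DEN 50 and 0.04 in DEN 100 at week 12. Vehicle array 24 alone gave 2283 for DEN 50 with vehicle, 776 for erlotinib 0.5, 960 for both doses, 582 for DEN 50 over time and 436 for the interaction.

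With an estimated correlation camera called 3 lists for DEN 50 and 9 for DEN 100 at week 12, 8 between the DEN doses, 9 for DEN 50 with vehicle, 1 for erlotinib 0.5, 6 for erlotinib 2, 1 between the erlotinib doses, 3 for both doses, 8 and 4 for erlotinib 0.5 and 2 against PBS, 0 for PBS over time, 4 for DEN 50 over time and 1 for the interaction. Genes of the signature lowered by DEN had a mean of 0.17 in both doses and missed the threshold of camera with an estimated correlation. Limma's fry called 1 list for erlotinib 0.5, 1 between the erlotinib doses, 13 for both doses, 0 for PBS over time, 8 for DEN 50 over time and 2 for the interaction. With the DEN 100 signature the erlotinib 0.5 means were -0.11 for raised and 0.14 for lowered genes.

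Leaving out 1 array gave 0 to 12 calls for PBS over time, 9 to 146 for DEN 50 over time, 11 to 75 for the interaction, 1201 to 1821 between the DEN doses, 3 to 40 for erlotinib 0.5, 333 to 663 for erlotinib 2, 1 to 29 between the erlotinib doses, 311 to 623 for both doses and 599 to 817 for erlotinib 2 against PBS. Lists ranged from 2 to 9 for PBS over time and from 10 to 17 for erlotinib 0.5. Signature means in erlotinib 0.5 ranged from -0.11 to 0.04 for raised and from -0.05 to 0.09 for lowered genes. Alb ranged from -0.10 to 0.05 in DEN 50 and from -0.49 to 0.01 in DEN 100 at week 12, Gstp1 in DEN 50 over time from -0.35 to 0.23, Col1a2 and Egfr with erlotinib 0.5 from -0.19 to 0.35 and from -0.11 to 0.48, Ccnd1 with erlotinib 2 from -0.44 to 0.26 and Afp at week 18 from -0.17 to 0.47.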

Other observations

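The tests of the clock genes other than Per2, of the gap between matrix and cell cycle scores, of a lower hepatocyte share and of genes matched for brightness, and the leaving out of arrays for the clock index, were chosen only after the result was seen.

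Immune and vessel markers beyond those described above also moved. In DEN 50 with vehicle against PBS at week 18, 6 of 11 mast cell genes rose, among them the chymase Cma1 by 1.98 ± 0.34 and Cpa3 by 1.58 ± 0.27 (limma's camera adjusted p = 0.00052, and adjusted p = 0.12 with an estimated correlation); the PBS liver expressed 3 of the 11 above the array median. Of 13 endothelial markers 6 rose (adjusted p = 0.052 with an estimated correlation), 11 of which the PBS liver also expressed. With erlotinib 2, 3 of 11 mast cell genes fell (adjusted p = 0.098 with an estimated correlation). The 10 housekeeping genes had a median of 0.45 after DEN at week 18 and 0.04 with bright-probe scaling, so their rise is not separable from the scaling.

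In erlotinib 2 livers the clock gene Per2 changed by -1.86 ± 0.34 (limma adjusted p = 0.0029) and Bmal1 by 0.65 ± 0.18 (adjusted p = 0.045) against vehicle. In DEN 50 with vehicle against PBS, Nr1d1 changed by -1.66 ± 0.47, Usp2 by -1.79 ± 0.49 and Dbp by -0.61 ± 0.12. No other clock gene of the index passed in these comparisons. The night genes lay between -0.15 (Bmal1) and 0.19 (Npas2) in DEN 50 with vehicle. With erlotinib 2, Nr1d1 had a change of 0.65 ± 0.47, Dbp of -0.09 ± 0.12 and Clock of -0.03 ± 0.13. The clock index was -0.75 ± 0.32 for erlotinib 2 and -0.40 ± 0.32 for erlotinib 0.5 against vehicle. The latter rested on array 79, without which it was 0.03, and it was -0.62 without array 73 and -0.61 without array 74.

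Genes changed by DEN, such as Gpc3 and Obp3, lay closer to PBS in the erlotinib 2 arrays. Shared vehicle arrays were argued against, because genes raised by DEN 50 at week 12, chosen without week 18 arrays, had a mean change of -0.36. Vehicle array 24 was argued against too as the source of the difference, since its score of 1.525 was the vehicle score nearest to erlotinib 2. Leaving it out could therefore only enlarge the difference, which was -0.85 instead of -0.69, a ratio of 1.23. The ratio says nothing about the other vehicle arrays. The study the rats came from cannot be told apart from the dose, since the labels name no study per rat; against single vehicle arrays the difference was -0.37 (array 24), -0.78 (array 59) and -0.91 (array 69). An action of erlotinib is a candidate explanation that the design names, and the study remains open beside it.

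Male-biased genes such as Cyp2c11 and Obp3 fell further than other hepatocyte genes in DEN 50 with vehicle against PBS. A lower share of hepatocytes was argued against as the sole cause, by a test chosen after the result was seen. The median of 13 male-biased genes was -2.44 and that of 67 genes of the secreted protein, urea cycle and bile acid lists -0.90, a difference of -1.54. The female-specific Cyp2c12 rose by 4.60 ± 0.36. For bright probes near the scanner limit a first test could not decide: 59 of the 67 genes lay in the wide PBS range of the male-biased genes (median -1.04, a difference of -1.40), so this range did not match brightness. Against the 3 hepatocyte genes nearest in PBS level, 12 of the 13 male-biased genes lay lower, by a median of -1.10 with quartiles of -4.39 and -0.77. Both quartiles lay on the same side. The upper quartile of -0.77 fell short of the size required to count brightness out, so this test could not decide either. The spread is wide, so a contribution of unknown size from brightness stays possible for the larger fall. Cyp2c12 is 1 of 8 measured female-biased genes, whose score was higher than with PBS by 0.77 without overlap (exact two-sided permutation p = 0.1). In DEN 50 at week 12 this list did not pass camera (adjusted p = 0.14). With erlotinib 2 its score differed from vehicle by 0.01, while the male-biased score was higher by 2.01. A loss of the male pattern of growth hormone signalling could also explain the larger fall, a hypothesis found and examined on the same data. Hormones were not measured.

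With erlotinib 2 the matrix score was lower than with vehicle, while the cell cycle score was 7.59 ± 0.07 (SD, n = 3) against 7.64 ± 0.34. The vehicle arrays spread widely, so a lower cell cycle score with erlotinib 2 stays possible. Relative to erlotinib 0.5 (7.94 ± 0.17) the cell cycle score was lower by -0.35 without overlap (exact two-sided permutation p = 0.1). There dose and study cannot be told apart. The gap between the scores differed from vehicle by -0.54 and, without vehicle array 24, by -0.43, with no overlap of arrays in either (exact p = 0.1, the smallest possible). Whether array 24 explained this gap was first listed among the explanations to weigh, written after the result was seen, and was then dropped to keep to 3 patterns.

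Other splits of the samples were counted for each comparison by limma calls. For both doses against vehicle, pooled as 1 group, only the real one of the 84 splits gave as many genes (470, the highest other 257). This is the smallest share that 84 splits allow, 0.0119, without correction over the comparisons split. It argues against chance for the gene count without excluding it. For lists 10 of the 84 gave as many (21, the highest other 25) and chance was not excluded. In both, the highest other split set the erlotinib 2 arrays apart. Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. The real value and the highest other were 2108 and 1 for DEN 50 against PBS at week 12, 4114 and 6 for DEN 100, 1815 and 2 between DEN doses, 3528 and 1 for DEN 50 with vehicle at week 18, 27 and 0 for erlotinib 0.5, 780 and 1 for erlotinib 2 and 15 and 1 between erlotinib doses. They were 2994 and 0 for erlotinib 0.5 against PBS, 1097 and 0 for erlotinib 2 against PBS, 29 raised plus 76 lowered and 24 for DEN 50 over time, and 0 and 4 for PBS over time (all 10 splits reached 0, with 1568 features at an unadjusted p under 0.05).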
